A study of Ovis aries with 91 samples.

How the data were processed

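Sequencing libraries were prepared with the Illumina NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument, per the labels. The submitters' processing notes name bcl2fastq, cutadapt, RSEM and limma, without versions, roles or order. The aligner, its settings, the genome build and the gene annotation are not given in the sources used here. The deposited tables hold 1 column per sheep and region on a log2 scale, so the technical replicates that the labels list were merged before deposit. A table each covers whole tissue of the appendages (13187 genes, 18 columns), isolated cardiomyocytes of the appendages (13262 genes, 18 columns) and the posterior left atrium (12141 genes, 12 columns), and 0 columns could not be tied to a sample.

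What the deposited log2 values hold was checked on the values. In the whole tissue and cardiomyocyte tables each value equals the log2 of a whole number of reads plus 0.5, divided by a scaled library size, on the CPM scale. All of the 237366 whole tissue values and 238716 cardiomyocyte values gave whole reads within 0.05 reads, so reads per library were recovered from the values. The scaling factors applied by the authors, found from the same values, lay between 0.828 and 1.14. Of 3685 low values of the posterior left atrium 11.1% fell on whole reads, so those log2 values were changed after the log was taken, by a step that the sources used here do not record. There 0.465% of genes had a p under 0.1 for a difference between the sets of sheep and 17.7% a p over 0.9, where 10% each would come from chance, so a difference between the sets had been removed before deposit; the depth is unknown and no reads were recovered.

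Listed reads per library were 6.24e+06 to 2.24e+07 in whole tissue and 5.31e+06 to 1.24e+07 in cardiomyocytes, and the 10 highest genes held 15.2% to 22.2% and 17.5% to 23.5% of them. Genes with a mean log2 CPM below 0 over the samples of a table were left out, which kept 12333, 12279 and 12035 genes. Genes that share reads with a near-identical copy or overlap another gene cannot be told apart here, and whether the counting used strand is not given in the sources used here.

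Samples were grouped by the condition, region and sheep in the labels. Control groups joined sheep labelled sham with sheep C1, which is labelled control and which the column names also call sham. Among posterior left atrium sheep, those with G numbers and those with S, C or D names differ in their technical replicate labels, and the transition sheep with G numbers are titled saline; the set was a term of the model. In the appendage tables the technical replicate labels are the same in every group, so they form no batch. Chi-square per degree of freedom between recovered reads of any pair of sheep in an appendage group was 10.9 or more, so within these groups no library was a copy of another within sampling noise. Libraries of different groups were not compared in this way.

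All tests used limma 3.58.1 in R 4.3.3, with a mean-variance trend, on the deposited log2 values and without a further pseudocount. In each appendage table a model of the 6 group means was fitted to all samples, and the sheep, which gave left and right samples, entered as a random effect through a consensus correlation of 0.294 in whole tissue and 0.470 in cardiomyocytes. The pairing comes from the sheep names in the labels, and both correlations show that samples of a sheep deviate together. The left against right contrast averaged over the 3 states, and differences of changes were tested as interaction contrasts. The posterior left atrium model held state and set. The p-values were adjusted by Benjamini-Hochberg over the genes of a table, with a threshold of 0.05. No test was made across tables, which were normalised separately, though the lists of tissue-enriched and cardiomyocyte-enriched genes rank differences between the whole tissue and cardiomyocyte tables. Count models planned for read tables were not run, as the deposited values are on a log2 scale, although whole reads could be recovered in the appendage tables. Voom weights on these recovered reads were used as an alternative instead.

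The comparisons, tests, alternatives and naming rule were fixed before the data were examined. The rule named, per comparison, the genes with the largest increases and decreases among those past the threshold, above the median level and with every sheep of a group beyond every sheep of the other, or, for left against right, the same direction in every sheep; as IDs carry no names here, at most 2 were printed per direction. The gene lists and cell type markers fixed before the data were examined are lists of symbols. They could not be used, since 0 IDs matched a symbol, and no result is given for them. The groups of tissue-enriched, cardiomyocyte-enriched, left-higher and right-higher genes were chosen after the data were seen. They were tested with camera, which sets a list against the other genes, at a preset correlation of 0.01 and at an estimated correlation, and with fry, which tests a list for a change as such and not against other genes, with adjustment over 76 tests. The tissue-enriched lists made from control, transition and chronic sheep shared 181 to 234 of 500 genes.

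The alternatives were no filter, pseudocounts of 0.1 and 10, quantile normalisation, median-of-ratios rescaling, sample quality weights, no sheep effect, sheep as a fixed factor, each appendage alone, no set term, each set alone and each sheep left out in turn. Voom and library totals without the authors' scaling were added after the data were seen. The models were tested on simulated data for transition against control. Of 100 genes changed by 1 log2 unit, 40 were recovered in left whole tissue, 47 in left cardiomyocytes and 77 in the posterior left atrium. Of 100 changed by 2 log2 units, 79, 87 and 97 were recovered, with 6, 13 and 7 false calls among unchanged genes.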

Results

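RNA was sequenced from sheep atria in which atrial fibrillation, a fast and irregular atrial rhythm, had been brought about by rapid pacing from a device in the right atrium. Sheep were labelled as control, transition or chronic, and the title of the series places these states along the progression of atrial fibrillation. Samples came from the left and right atrial appendages, as whole tissue or as isolated cardiomyocytes, the contracting muscle cells, and from the posterior left atrium. Each of the 6 groups of appendage samples held 3 sheep in the whole tissue table and 3 in the cardiomyocyte table, and 7 sheep gave samples to both tables. The posterior left atrium was sampled in 6 control and 6 transition sheep, of which 5 also gave appendage samples. The control groups joined sheep labelled sham with sheep C1, labelled control. The depth was 6.24e+06 to 2.24e+07 listed reads per sample in whole tissue and 5.31e+06 to 1.24e+07 in cardiomyocytes, while the depth behind the posterior left atrium values is unknown. Gene-by-gene correlations between sheep of the same group lay between 0.935 and 0.973 over all groups (Pearson's r across genes, which are not independent replicates), so no pair of sheep within a group looked like a library deposited again.

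In whole tissue the control sheep lay apart from the paced sheep on the first principal component, which held 21.2% of the variance. Control samples scored −40.4 to −22.9 on it, and the lowest score of a paced sample was −10.4, in the right appendage of transition sheep D30. In cardiomyocytes the states overlapped on the first component, with 24.3% of the variance. There left transition sheep D24 and D27 scored −42.3 and −58.9 and D23 −7.72. In the right appendage D16, D19 and D23 scored 27.7 to 39.4, and D20, D24 and D27 −24.8 to −1.69. The states separated mainly on the second component, with 16.3% of the variance. Control samples scored −36.2 to −8.61 there and chronic samples 9.25 to 35.8, with transition samples at −7.42 to 15.1. On the first component of the posterior left atrium control sheep scored −35.2 to −17.4 against 17.9 to 33.4 in transition sheep.

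**Figure D1:**
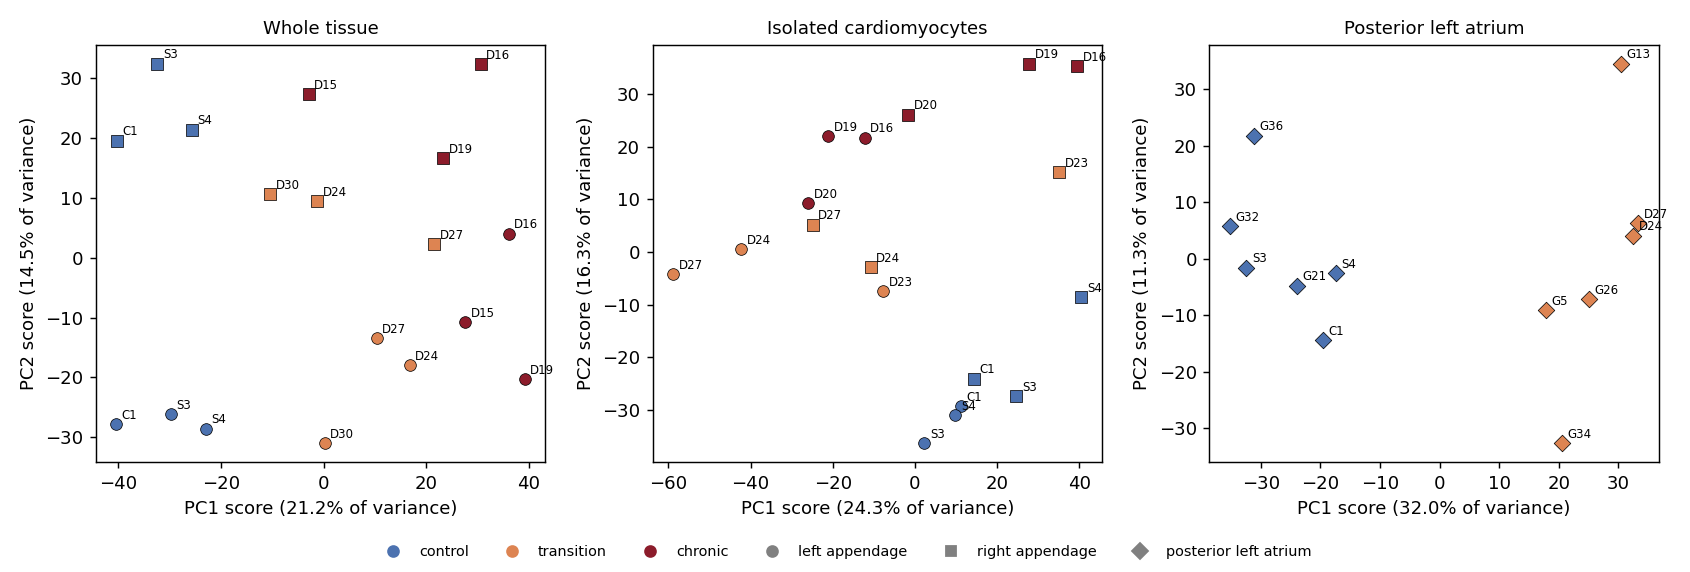
Scores of each sample on the first and second principal components of the log2 values, in whole tissue, isolated cardiomyocytes and posterior left atrium, with the share of variance (%) on each axis; colours mark the state, shapes the region and text the sheep. Control samples lie at −40.4 to −22.9 on the first component in whole tissue and at −35.2 to −17.4 in the posterior left atrium.

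The deposited tables list Ensembl sheep gene IDs and do not pair them with gene names, and 0 of the IDs matched a symbol in the reference table used here, so genes are named by ID and no pathway is named. Groups of genes were instead defined from the data. Tissue-enriched and cardiomyocyte-enriched genes were the 500 genes highest and the 500 lowest in whole tissue relative to cardiomyocytes of the same sheep, and for each comparison they were taken from sheep of a state that the comparison did not use, except for left against right. Lists from transition sheep, used for chronic against control, rest on 2 sheep, D24 and D27. Lists from chronic sheep, used for transition against control and the posterior left atrium, rest on 2 sheep, D16 and D19. Lists from controls rest on 3 sheep. Left-higher and right-higher genes were those past the threshold between the appendages in the other appendage table, or in the whole tissue table for the posterior left atrium. Most of these lists come from the same animals, so they are not independent evidence. Genes are called changed at an adjusted p of 0.05 in limma, with Benjamini-Hochberg adjustment over the genes of a table, and changes are given on the log2 scale with their standard errors. The p-values rest on the spread between these sheep, which in the appendage tables is pooled over both sides and all states. With each appendage fitted alone the left counts against control stayed within 1.5 times of those reported. The right counts fell below that range, as given with each comparison.

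**Figure D2:**
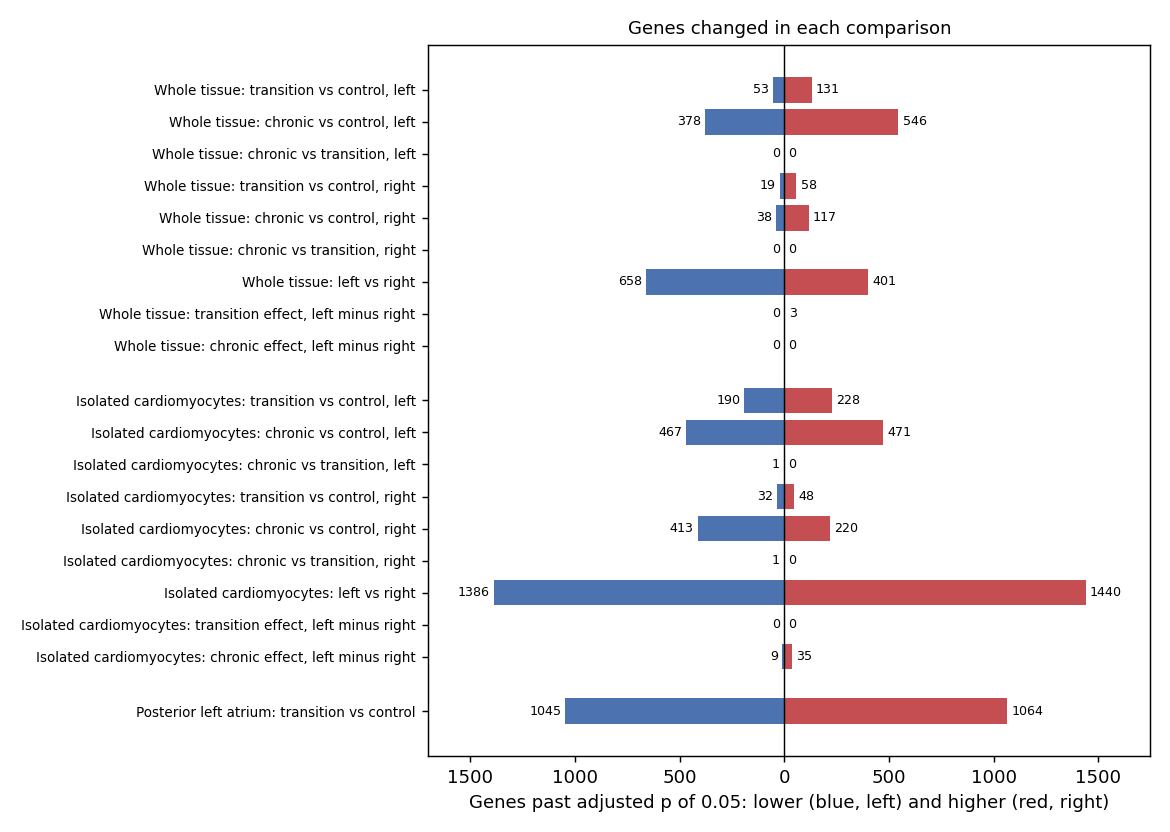
Number of genes past an adjusted p of 0.05 in limma for each comparison, with lower genes as blue bars to the left and higher genes as red bars to the right of 0. The chronic comparison called 546 higher and 378 lower genes in left whole tissue, and the posterior left atrium 1064 higher and 1045 lower.

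The transition comparison asks which genes had already moved before the chronic state. In left appendage whole tissue 131 genes were higher and 53 lower in transition sheep than in controls. The increase of ENSOARG00000012673 was 3.65 ± 0.32 (SE), from a mean log2 CPM of 3.90 ± 0.27 (SD, n = 3) in controls to 7.55 ± 0.33 (SD, n = 3), a 12.5-fold rise. ENSOARG00000000248 rose by 3.41 ± 0.46. ENSOARG00000000476 fell by 2.41 with a standard error of 0.36, from 6.92 ± 0.19 to 4.52 ± 0.31 (SD, n = 3). Of the 500 tissue-enriched genes 9 were higher, 1 was lower and 490 did not pass, with a median change of 0.17 (camera adjusted p = 0.000487, adjusted p = 0.491 with an estimated correlation, and fry adjusted p = 0.314). In all, limma called 184 of 12333 genes, and 529 with sample quality weights. The call of ENSOARG00000013633 (−2.21 ± 0.54, adjusted p = 0.0490) was lost without any single sheep of the comparison, with its change then between −2.56 and −1.92, and also with each appendage fitted alone, library totals, median-of-ratios rescaling, the sheep left out of the model, quantile normalisation or voom. The count of genes was 104 without C1, 51 without S3, 62 without S4, 33 without D24 and 51 without D27.

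In the left appendage of chronic sheep more genes lay past the threshold, 546 higher and 378 lower than in controls in whole tissue. ENSOARG00000012673 was again among them, with a rise from 3.90 ± 0.27 to 7.90 ± 0.70 (SD, n = 3). ENSOARG00000007684 fell by 2.78, from 6.12 ± 0.75 to 3.34 ± 0.50 (SD, n = 3), and ENSOARG00000010539 fell by 2.46. The highest increases under the naming rule, ENSOARG00000008817 (4.62 ± 1.25) and ENSOARG00000010493 (4.42), varied widely between control sheep, with SDs of 2.70 and 2.75. Of the 500 tissue-enriched genes 30 were higher and 27 lower, and the list did not pass its test (median 0.061, camera adjusted p = 0.496, adjusted p = 0.907 with an estimated correlation, and fry adjusted p = 0.807). By limma 924 of 12333 genes passed. Without C1, D15, D16 or D19 neither of these increases stayed past the threshold, and without S3 that of ENSOARG00000008817 was lost as well, with changes of 3.79 to 6.17 and 2.84 to 5.31 over all left-out sheep. Both calls were also lost with the sheep left out of the model, and that of ENSOARG00000008817 with the left appendage fitted alone or sample quality weights; the count of genes was 450 without C1, 550 without S3, 526 without S4 and 435 without D19. With library totals in place of the authors' scaling the split turned to 409 higher and 561 lower.

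In right appendage whole tissue 58 genes were higher and 19 lower in transition sheep. ENSOARG00000012673 rose by 2.80 ± 0.32 and ENSOARG00000020383 by 2.71 ± 0.31, the latter from 4.56 ± 0.57 to 7.27 ± 0.37 (SD, n = 3). ENSOARG00000022521 fell by 1.38 and ENSOARG00000024133 by 1.36. Genes that were higher on the left in cardiomyocytes tended upward in the right appendage of transition sheep, where 31 of 1415 rose and 0 fell (median 0.24, camera adjusted p = 4.91e-14, adjusted p = 0.0501 with an estimated correlation, and fry adjusted p = 0.0348). Of the 1282 right-higher genes 0 rose and 4 fell, with a median of −0.31 (camera adjusted p = 1.11e-14, adjusted p = 0.0294 with an estimated correlation, and fry adjusted p = 0.0300). The limma test called 77 of 12333 genes, and with library totals 32 higher and 17 lower, or 44 higher and 30 lower with a pseudocount of 10 and 60 higher and 38 lower with voom. The right appendage fitted alone gave 14 genes and sample quality weights 700. The count was 35 without C1, 27 without S3, 50 without S4, 27 without D24, 19 without D27 and 46 without D30, and the decreases of both named genes lost their calls without C1, S3, D24 or D30, at changes of −1.66 to −1.22 for ENSOARG00000022521 and −1.62 to −1.13 for ENSOARG00000024133 over all left-out sheep, and both also with the right appendage fitted alone.

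In the right appendage of chronic sheep 117 genes were higher and 38 lower in whole tissue. ENSOARG00000012673 reached 7.33 ± 0.74 (SD, n = 3), a change of 3.48 ± 0.32, and ENSOARG00000000248 rose by 3.21 ± 0.46. ENSOARG00000007684 fell by 2.37 and ENSOARG00000010539 changed by −1.75, genes that also fell in the left appendage. Of the 1415 left-higher genes 45 rose and 2 fell (median 0.19, camera adjusted p = 5.27e-09, adjusted p = 0.146 with an estimated correlation, and fry adjusted p = 0.0727). Of the 500 tissue-enriched genes, another list than in transition sheep, 2 were higher and 6 lower, with a median of −0.16 (camera adjusted p = 0.000567, adjusted p = 0.469 with an estimated correlation, and fry adjusted p = 0.376). By limma 155 of 12333 genes passed, with 70 higher and 50 lower under library totals. The right appendage fitted alone gave 36 genes and sample quality weights 774. The count rose to 428 without D15 and was 40 without C1, 75 without S3, 64 without S4, 38 without D16 and 49 without D19; the call of ENSOARG00000010539 was lost without C1 or D16, with a change of −1.38 at the weakest over all left-out sheep, and with the right appendage fitted alone.

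No gene passed between chronic and transition sheep in whole tissue in either appendage under the chosen model, though some alternatives called genes. In the left appendage limma called 0 of 12333 genes, with 1352 at an unadjusted p under 0.05, and voom on recovered reads called 0. In the right appendage limma also called 0, with 747 at an unadjusted p under 0.05, and voom called 0. Sample quality weights called 35 genes on the left and 126 on the right, a pseudocount of 10 called 9 on the left and the left appendage fitted alone 8. The 500 cardiomyocyte-enriched genes leaned upward in chronic against transition sheep, with a median of 0.27 on the left (camera adjusted p = 3.21e-07, adjusted p = 0.0501 with an estimated correlation, and fry adjusted p = 0.0441) and 0.27 on the right (camera adjusted p = 4.07e-08, adjusted p = 0.0345 with an estimated correlation, and fry adjusted p = 0.0570), though 0 of them passed gene by gene. The tissue-enriched genes leaned downward on the left, with a median of −0.17 (camera adjusted p = 5.78e-05, adjusted p = 0.144 with an estimated correlation, and fry adjusted p = 0.0956), and on the right their median was −0.042 (camera adjusted p = 0.536, adjusted p = 0.848 with an estimated correlation, and fry adjusted p = 0.807). A change in the share of cardiomyocytes in the tissue could not be told from a change within cells here, as no cell type markers could be matched. The left count was 2 without D15, 11 without D16, 1 without D27 and 1 without D30, and the right count 1 without D15, 2 without D19 and 1 without D30.

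In isolated left cardiomyocytes 228 genes were higher and 190 lower in transition sheep than in controls. ENSOARG00000017646 rose by 2.57 ± 0.45 and ENSOARG00000017779 by 2.31 ± 0.44, the latter from 8.34 ± 0.98 to 10.65 ± 0.38 (SD, n = 3). ENSOARG00000003826 fell by 2.75, from 7.26 ± 0.76 to 4.51 ± 0.34 (SD, n = 3), and ENSOARG00000007984 changed by −2.38. Of the 500 cardiomyocyte-enriched genes 2 rose and 54 fell, with a median of −0.48 (camera adjusted p = 4.99e-13, adjusted p = 0.109 with an estimated correlation, and fry adjusted p = 0.0290). The median of the 593 right-higher genes was −0.66, and 1 rose while 20 fell (camera adjusted p = 7.10e-15, adjusted p = 0.283 with an estimated correlation, and fry adjusted p = 0.103). Of 12279 genes limma called 418, and 1214 with sample quality weights, where the balance turned to 555 higher and 659 lower. The count rose to 1287 without D23, with 535 higher and 752 lower, and was 141 without C1, 110 without S3, 121 without S4, 89 without D24 and 95 without D27; the call of ENSOARG00000017779 was lost without S3, with changes of 1.85 to 2.83 over all left-out sheep.

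In left cardiomyocytes of chronic sheep 471 genes were higher and 467 lower. The genes named for transition sheep led here too, with ENSOARG00000017646 up by 3.33 ± 0.45 and ENSOARG00000017779 up by 3.06 ± 0.44, to 11.40 ± 0.31 (SD, n = 3). ENSOARG00000003826 fell by 3.10 and ENSOARG00000007984 by 3.02. Of the 500 cardiomyocyte-enriched genes 17 rose and 67 fell, with a median of −0.22 (camera adjusted p = 1.36e-05, adjusted p = 0.0501 with an estimated correlation, and fry adjusted p = 0.0191). In whole tissue of chronic sheep the same list leaned the other way. On the left 47 rose and 14 fell, with a median of 0.067 (camera adjusted p = 0.107, 0.763 with an estimated correlation, fry adjusted p = 0.584). On the right 9 rose and 1 fell, with a median of 0.15 (camera adjusted p = 0.0454, 0.734 with an estimated correlation, fry adjusted p = 0.538). The limma test called 938 of 12279 genes, and with library totals the split was 299 higher and 760 lower. Sample quality weights gave 1791 genes. The count was 440 without C1, 450 without S3, 450 without S4, 477 without D16, 319 without D19 and 608 without D20.

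In right cardiomyocytes 48 genes were higher and 32 lower in transition sheep. ENSOARG00000020383, which also rose in right whole tissue, rose by 2.99 ± 0.34, and ENSOARG00000005034 by 2.25 ± 0.32, from 4.70 ± 0.58 to 6.95 ± 0.21 (SD, n = 3). ENSOARG00000003826 fell by 2.43 and ENSOARG00000003354 by 1.89. Of the 500 cardiomyocyte-enriched genes 2 rose and 11 fell, with a median of −0.19 (camera adjusted p = 5.81e-05, adjusted p = 0.423 with an estimated correlation, and fry adjusted p = 0.314). The limma test called 80 of 12279 genes, 52 with the sheep left out of the model, 9 with the right appendage fitted alone and 409 with sample quality weights. The count rose to 300 without D23 and was 26 without C1, 21 without S3, 22 without S4, 28 without D24 (10 higher and 18 lower) and 9 without D27; the call of ENSOARG00000003354 was lost without C1, S3, D24 or D27, with changes of −2.21 to −1.46 over all left-out sheep, and with the right appendage fitted alone or the sheep left out of the model.

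In right cardiomyocytes of chronic sheep more genes fell than rose, with 220 higher and 413 lower. ENSOARG00000020383 rose by 2.74 ± 0.34 and ENSOARG00000017779 by 2.66 ± 0.44. ENSOARG00000003826 fell by 2.69, to 3.81 ± 0.19 (SD, n = 3), and ENSOARG00000003354 fell by 2.36. Of the 500 cardiomyocyte-enriched genes 11 rose and 65 fell, while the list passed none of its tests (median −0.0049, camera adjusted p = 0.0501, adjusted p = 0.462 with an estimated correlation, and fry adjusted p = 0.219). The tissue-enriched genes had a median of 0.27 here and −0.24 in left chronic cardiomyocytes. For the left minus right difference of the chronic change their median was −0.47 (camera adjusted p = 1.24e-11, adjusted p = 0.365 with an estimated correlation, and fry adjusted p = 0.289). The limma test called 633 of 12279 genes, and with library totals the excess of lower genes was gone, at 332 higher and 326 lower. With the right appendage fitted alone 159 genes passed. The count was 328 without C1, 97 without S3, 337 without D16, 170 without D19 and 279 without D20.

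Chronic and transition cardiomyocytes differed by 1 gene past the threshold, ENSOARG00000002796, which was called in both appendages and is named here after its values were seen. It had 0 to 1 reads in the cardiomyocytes of the 3 chronic sheep and 82 to 381 in those of transition sheep. In limma 1 of 12279 genes passed in the left appendage, with 865 at an unadjusted p under 0.05, and 1 passed in the right, with 1098 at an unadjusted p under 0.05. In whole tissue chronic sheep D15 had 268 to 285 reads of it and D16 and D19 had at most 2, and it was not called there. With a pseudocount of 10 no gene passed on the left, which ended the call there, and 3 passed on the right. Each appendage fitted alone, no filter and voom gave 2 genes on each side, and sample quality weights 2 on the left and 11 on the right. The left count was 15 without D23, and the right count 84 without D23 and 3 without D20.

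**Figure D3:**
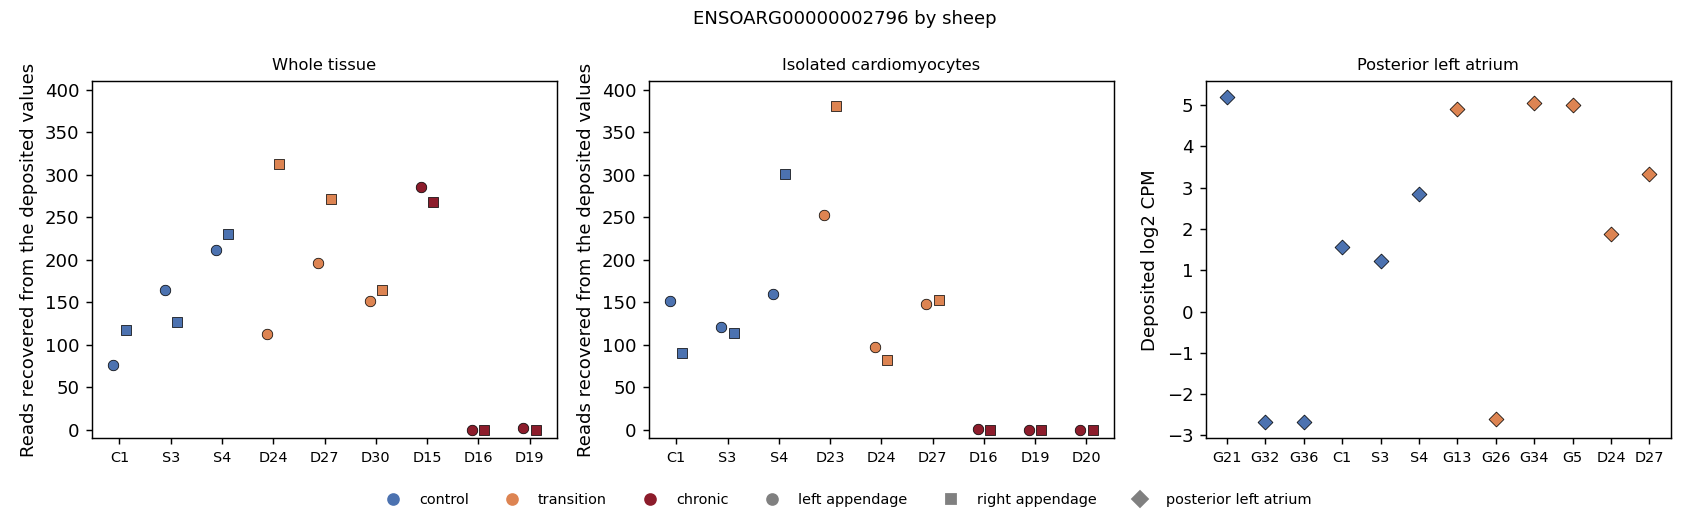
ENSOARG00000002796 by sheep, as reads recovered from the deposited values in whole tissue and isolated cardiomyocytes and as deposited log2 CPM in the posterior left atrium; colours mark the state and shapes the region. Sheep D16, D19 and D20 have at most 2 reads in every library, and the other sheep of the appendage tables have 76 to 381.

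The left and right appendages were compared within the 9 sheep of each table. In whole tissue 401 genes were higher on the left and 658 on the right, and in cardiomyocytes 1440 were higher on the left and 1386 on the right. ENSOARG00000019859 was far higher on the right, with 13459 to 63696 reads per right sample and 4 to 113 per left sample in whole tissue, and 4138 to 20410 against 2 to 29 in cardiomyocytes. Its difference was −10.60 ± 0.37 in whole tissue and −10.65 ± 0.33 in cardiomyocytes (left minus right). In whole tissue ENSOARG00000014874 was also lower on the left by 2.45, and ENSOARG00000017490 (1.71 ± 0.19) and ENSOARG00000019153 (1.55 ± 0.28) were higher on the left. In cardiomyocytes ENSOARG00000007268 (2.89 ± 0.25) and ENSOARG00000012705 (2.26 ± 0.18) were higher on the left and ENSOARG00000018367 was lower by 1.97.

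The side differences of whole tissue and cardiomyocytes overlapped. Of the genes tested in whole tissue and in cardiomyocytes, 253 were higher on the left in each, where 47.0 would be shared by independent lists of these sizes, and 355 were higher on the right in both, against 64.4, with 8 of opposite sign. Because 7 sheep gave samples to both tables, part of the overlap can come from shared animals. Of the 500 tissue-enriched genes 4 were higher and 112 lower on the left in whole tissue, with a median of −0.17 (camera adjusted p = 1.11e-14, adjusted p = 0.0140 with an estimated correlation, and fry adjusted p = 0.00101); this list was made from the same samples. In limma the calls were 1059 of 12333 genes in whole tissue and 2826 of 12279 in cardiomyocytes, and 478 and 773 with the sheep left out of the model. Sample quality weights gave 2043 in whole tissue. Library totals gave 167 higher and 1427 lower on the left in whole tissue, and 727 and 2091 in cardiomyocytes; the whole tissue count was 614 without D15, 685 without D19, 664 without D24 and 702 without D30, and the cardiomyocyte count 1871 without S4.

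Whether a state changed the appendages differently was tested as the difference of the changes. In whole tissue the transition change was larger on the left for 3 genes, named here after their values were seen. The left minus right difference was 6.86 for ENSOARG00000015333, which had 40 to 172 reads in left transition samples and 0 to 4 in left controls. It was 3.26 for ENSOARG00000014321 and 3.09 for ENSOARG00000010633. In limma 3 of 12333 genes passed, and 1 by voom, with 0 genes without C1, S4, D24 or D27, 16 without D30, 1 with the sheep left out of the model, 1 with quantile normalisation, 0 with a pseudocount of 10 and 67 with sample quality weights. For the chronic change in whole tissue limma called 0 genes, with 815 at an unadjusted p under 0.05, and voom called 0, while 1 passed without S3 and 2 with sheep as a fixed factor.

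In cardiomyocytes the chronic change differed between the appendages for 44 genes, of which 27 lay above control on the left and below it on the right. ENSOARG00000017557 differed by 2.03 ± 0.35, with left means of 3.17 ± 0.56 in controls and 5.83 ± 0.13 in chronic sheep (SD, n = 3) and right means of 4.09 ± 0.54 and 4.73 ± 0.68. ENSOARG00000012373 differed by 1.82 ± 0.36. The differences were −1.31 for ENSOARG00000007984 and −1.13 for ENSOARG00000007725, and the call of each of these 4 genes was lost without C1, S3, S4, D16 or D19. Their differences over all left-out sheep ran from 1.71 to 2.31, from 1.40 to 2.18, from −1.41 to −1.16 and from −1.29 to −0.984, in the same order. All 4 calls were also lost with the sheep left out of the model, those of ENSOARG00000012373, ENSOARG00000007984 and ENSOARG00000007725 with quantile normalisation, those of ENSOARG00000012373 and ENSOARG00000007984 with library totals, those of ENSOARG00000007984 and ENSOARG00000007725 with voom, and that of ENSOARG00000007984 without a filter. The limma test called 44 of 12279 genes, and 1 without C1, 6 without S3, 11 without S4, 4 without D16, 2 without D19 and 102 without D20. With the sheep left out of the model 1 gene passed, with sheep as a fixed factor 82, with quantile normalisation 26 and with sample quality weights 168, and library totals split the calls as 9 higher and 10 lower against 35 and 9. For the transition change limma called 0 genes in cardiomyocytes, with 781 at an unadjusted p under 0.05, and voom called 0, against 3 without D23, 2 without D24 and 1 with sheep as a fixed factor.

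The transition and chronic changes ran the same way in each appendage. In left whole tissue 91 genes rose and 39 fell in both comparisons, where 5.80 and 1.62 would be shared by independent lists, and in left cardiomyocytes 183 rose and 122 fell in both, against 8.75 and 7.23. On the right 43 rose and 8 fell in both in whole tissue, against 0.550 and 0.0585, and 36 rose and 27 fell in both in cardiomyocytes, against 0.860 and 1.08. In these 4 pairs of comparisons 0 genes were called with opposite signs. The changes correlated across genes at r of 0.694 and 0.716 in left whole tissue and left cardiomyocytes, and at 0.666 and 0.602 on the right. Unchanged groups simulated with shared controls gave 0.499, 0.494, 0.497 and 0.506 in that order, with 0 shared calls in all 4 cases over 20 runs each. All sheep, controls included, were drawn anew there, with genes independent of each other. Such data give almost no calls, so the 0 shared calls are no benchmark for the shared genes. The covariance exceeded the simulated covariance by 0.177, 0.161, 0.110 and 0.0786. With 3 controls per group the controls could not be divided, so part of the excess of shared calls may come from the controls.

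The shared counts moved with single sheep. In left whole tissue 130 genes were shared, and 71 without C1, 41 without S3, 52 without S4, 30 without D24, 42 without D27, 202 without D15 and 83 without D19. In right whole tissue 51 were shared, and 24 without C1, 23 without S3, 33 without S4, 20 without D24, 16 without D27, 98 without D15, 23 without D16 and 18 without D19. In left cardiomyocytes 305 were shared, and 106 without C1, 96 without S3, 98 without S4, 620 without D23, 75 without D24, 83 without D27, 178 without D16 and 153 without D19. In right cardiomyocytes 63 were shared, and 24 without C1, 16 without S3, 20 without S4, 145 without D23, 27 without D24, 8 without D27, 30 without D16, 17 without D19 and 29 without D20.

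In the posterior left atrium 1064 genes were higher and 1045 lower in transition sheep than in controls. ENSOARG00000005034 rose by 3.26 ± 0.15, from 5.74 ± 0.35 to 8.94 ± 0.30 (SD, n = 6), and ENSOARG00000018211 by 3.43 ± 0.53; control sheep G32 lay at 5.06 for ENSOARG00000005034, below the other controls, of which the lowest lay at 5.69. ENSOARG00000009412 fell by 2.73, from 6.28 ± 0.47 to 3.61 ± 0.81 (SD, n = 6), and ENSOARG00000019421 by 2.38; transition sheep G26 lay at 5.20 for ENSOARG00000009412 against 3.11 to 3.68 in the others. Genes higher in the right appendage fell, with 12 of 574 higher, 245 lower and a median of −0.62 (camera adjusted p = 7.77e-24, adjusted p = 0.0294 with an estimated correlation, and fry adjusted p = 0.00182). Of the 394 left-higher genes 98 rose and 19 fell, with a median of 0.17 (camera adjusted p = 5.49e-06, adjusted p = 0.109 with an estimated correlation, and fry adjusted p = 0.00611). Of the 450 measured cardiomyocyte-enriched genes 28 rose and 71 fell (camera adjusted p = 0.00456, adjusted p = 0.240 with an estimated correlation, and fry adjusted p = 0.0348).

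The sheep of the posterior left atrium fell into 2 sets, which the labels set apart by sheep numbers and technical replicates, and limma was fitted with the set as a term. It called 2109 of 12035 genes. Within the set with G numbers alone, 4 transition against 3 control sheep, 731 genes passed, and within the other set, 2 against 3, 243 passed. In the G set every transition sheep was titled saline and no control sheep was. The state and whatever this title stands for cannot be told apart there, in this and every other result of the G sheep alone. Of the 731 genes 700 had the same sign in the other set, a share of 95.8%, and 147 genes passed in both sets, all with the same sign, where 14.8 would be shared by independent lists. The call of ENSOARG00000018211 was lost in the set without G numbers.

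The changes of the posterior left atrium were partly met in the appendages of other animals. None of the G sheep gave an appendage sample. Of the genes called in the G sheep and in left cardiomyocytes of transition sheep 96 were higher in both and 30 lower in both, where 8.17 and 4.65 would be shared by independent lists, and 2 had opposite signs. With right whole tissue 28 were higher and 10 lower in both, against 2.03 and 0.402, with 0 of opposite sign. With left whole tissue 32 were higher and 12 lower in both, against 4.24 and 1.31, but 4 had opposite signs and the changes correlated at r = 0.381 across genes. With right cardiomyocytes 18 were higher in both against 1.74, while 1 was lower in both against 0.745, no more than chance gives.

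Some genes were called in many of the comparisons. ENSOARG00000012673 was called in all 4 comparisons with control in whole tissue, and in cardiomyocytes it rose by 1.27 ± 0.21 and 1.67 ± 0.21 in left transition and chronic samples and by 0.91 ± 0.21 in right chronic samples, while its change of 0.76 ± 0.21 in right transition samples did not pass (adjusted p = 0.113). In the posterior left atrium it rose by 2.22 ± 0.24. ENSOARG00000003826 was called lower in all 4 comparisons with control in cardiomyocytes. Levels of single genes are not set side by side between tables, which were normalised separately; the tissue-enriched and cardiomyocyte-enriched lists do rest on ranks of differences between the tables.

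**Figure D4:**
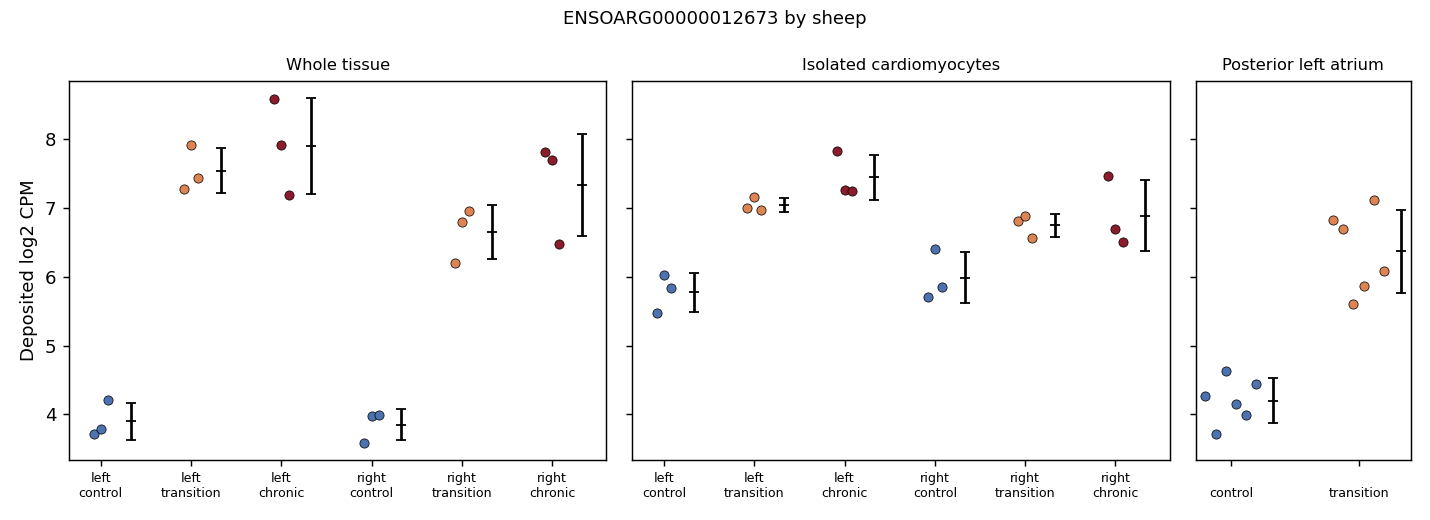
Deposited log2 CPM of ENSOARG00000012673 in each sheep (points) with the mean and SD of each group (bars), for whole tissue, isolated cardiomyocytes and posterior left atrium. In left whole tissue the control sheep lie at 3.71 to 4.21 and the transition sheep at 7.28 to 7.91.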

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

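The tests of whether the appendages changed differently were planned and the search for samples that stood apart followed a rule fixed beforehand; the test of whether the sets of posterior left atrium sheep changed differently, the reads of single genes and the counts over other groupings of the sheep were chosen only after the results were seen.

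A sample far from the rest was searched for in 16 groups of values of named genes, levels per state in the posterior left atrium and side differences per sheep in the appendages, and chance alone marks about 1 group in 20. Control sheep G32 stood apart for ENSOARG00000005034, with a log2 CPM of 5.06 against at least 5.69 in the other controls, a gap of 0.671 of the whole range. Transition sheep G26 stood apart for ENSOARG00000009412, with 5.20 against 3.11 to 3.68 and a gap of 0.726.

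In whole tissue the transition change differed between the appendages for 3 genes, ENSOARG00000010633 (3.09), ENSOARG00000014321 (3.26) and ENSOARG00000015333 (6.86). With 3 sheep against 3 there are 10 groupings, too few for a share under 0.05; the real grouping gave 3 genes (1 of 10 groupings gave as many) and the highest other gave 0. Left transition samples held 38 to 96 reads of ENSOARG00000010633 and 37 to 83 of ENSOARG00000014321, against 10 to 25 and 7 to 9 in left controls.

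In cardiomyocytes the chronic change differed between the appendages for 44 genes. Of these 32 had opposite signs on the 2 sides, 27 of them up on the left and down on the right, and the median changes over the 44 genes were 0.63 on the left and −0.36 on the right. The 10 groupings were again too few for a share under 0.05, with 44 genes in the real grouping and 0 in the highest other. The count was 1 without C1 and 102 without D20.

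In the posterior left atrium 1 gene, ENSOARG00000019361, changed differently in the sets of sheep, by 0.22 in the G sheep and by −6.05 in the other set. Its log2 CPM was 4.13 to 4.55 in controls C1, S3 and S4 and −1.78 to −1.57 in transition sheep D24 and D27, against 1.48 to 3.50 in the G sheep. In whole tissue it had 0 to 1 reads in D24 and D27 and 0 in chronic sheep D15, while the cardiomyocytes of D24 and D27 held 18 to 38 reads. The search for mixed-up samples below compared left with right libraries of the same material only. It could not show a mismatch between whole tissue and cardiomyocytes, so a mix-up of D24 or D27 between these was not tested.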

How the results depend on the processing

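Voom and library totals were chosen only after the data were seen, and the other alternatives were planned. First technical replicates alone, separate technical replicates and the fixed gene lists were not run, since the deposited columns merge the replicates and carry IDs without names. Count models were not run either, as the deposited values are log2 values, although whole reads could be recovered in the appendage tables. No named gene and none of the 14 gene groups run through the alternatives changed its sign in any of them, but the balance of higher and lower calls did turn. The naming rule took genes whose sheep separated completely, so with a sheep left out their signs could not turn. Their constant sign is therefore no sign of stability there. With library totals it turned from 546 higher and 378 lower to 409 and 561 in left chronic whole tissue, from 220 and 413 to 332 and 326 in right chronic cardiomyocytes, from 35 and 9 to 9 and 10 for the side difference of the chronic change and from 1440 and 1386 to 727 and 2091 for left against right in cardiomyocytes. Near-even splits also turned in other alternatives, among them left transition cardiomyocytes with 555 higher and 659 lower under sample quality weights. Counts of genes stayed within 1.5 times of the reported value in 177 of the tried combinations of result and alternative and left that range in 52, and with a sheep left out they stayed in 57 and left it in 105. Named genes kept their side of the threshold in 448 combinations and lost it in 28, and in 286 and 50 with a sheep left out. The 14 gene groups run through the alternatives had been picked for passing camera at the preset correlation and fry, and by the former they kept their side in 136 and lost it in 1, the cardiomyocyte-enriched genes of the posterior left atrium in the set without G numbers, and kept it in all 120 with a sheep left out. For these counts the camera p was not adjusted, and the lists were kept as first made under every alternative. These counts do not make the group calls stable, since the choice of test mattered more. Of all 76 group tests 55 passed camera at the preset correlation, 8 at an estimated correlation and 14 fry, and of the 14 groups 7 passed at an estimated correlation.

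The counts that left the range are given here, and the cause was not tested except where sheep or terms were removed, which leaves fewer samples or another spread. With sample quality weights, whole tissue gave 529 genes for transition and 35 for chronic against transition on the left, 700, 774 and 126 for transition, chronic and chronic against transition on the right, 2043 for left against right, 67 for the difference of the transition change between sides, and 353 and 323 shared by transition and chronic on the left and right. Cardiomyocytes gave 1214, 1791 and 2 for transition, chronic and chronic against transition on the left, 409 and 11 for transition and chronic against transition on the right, 2 and 168 for the side differences of the transition and chronic changes, and 750 and 176 shared.

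Without the replicate block (sheep left out of the model) whole tissue gave 478 genes for left against right and 1 for the side difference of the transition change, and cardiomyocytes 52 for right transition, 773 for left against right and 1 for the side difference of the chronic change. With a fixed replicate block the side difference of the chronic change gave 2 genes in whole tissue and 82 in cardiomyocytes, and that of the transition change 1 in cardiomyocytes; it moved no other count beyond the range. With each appendage fitted alone whole tissue gave 8 for left chronic against transition, 14 and 36 for right transition and chronic, and 12 shared on the right, and cardiomyocytes 2 and 2 for chronic against transition on the left and right, 9 and 159 for right transition and chronic, and 9 shared. Left transition and chronic counts, fitted with as few samples, stayed within the range at 172 and 1021 in whole tissue and 339 and 788 in cardiomyocytes. The right appendage calls thus depend on the pooled spread.

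With a pseudocount of 10, chronic against transition gave 9 genes in left whole tissue and 0 and 3 in left and right cardiomyocytes, and the side difference of the transition change 0 and 1 in whole tissue and cardiomyocytes. Quantile normalisation gave 1 for that difference in whole tissue and 26 for the chronic one in cardiomyocytes. Voom gave 1 for the former. Chronic against transition in left and right cardiomyocytes gave 2 and 2 with voom and also without a filter. Library totals gave 49 for right transition and 1594 for left against right in whole tissue and 19 for the side difference of the chronic change in cardiomyocytes. They shifted the median over all genes by −0.147 for left chronic against transition, −0.120 for left against right and 0.110 for the side difference of the transition change in whole tissue, and by −0.114 for left chronic and −0.177 for the side difference of the chronic change in cardiomyocytes. In the posterior left atrium 731 genes passed in the G sheep alone and 243 in the other set alone, with fewer sheep each.

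With a sheep left out, a group of 2 sheep relied on the spread pooled over groups. In whole tissue counts ran from 33 (D24) to 146 (D30) for left transition, 435 (D19) to 933 (D15) for left chronic, 19 (D27) to 50 (S4) for right transition, 38 (D16) to 428 (D15) for right chronic, 0 to 11 (D16) and 0 to 2 (D19) for chronic against transition on the left and right, 614 (D15) to 1318 (D27) for left against right, 0 to 16 (D30) and 0 to 1 (S3) for the side differences of the transition and chronic changes, and 30 (D24) to 202 (D15) and 16 (D27) to 98 (D15) for shared genes. In cardiomyocytes they ran, in the same order, from 89 (D24) to 1287 (D23), 319 (D19) to 608 (D20), 9 (D27) to 300 (D23), 97 (S3) to 462 (S4), 1 to 15 (D23), 1 to 84 (D23), 1871 (S4) to 3175 (D20), 0 to 3 (D23), 1 (C1) to 102 (D20), 75 (D24) to 620 (D23) and 8 (D27) to 145 (D23). For the posterior left atrium they ran from 1431 (G32) to 2175 (G34), within the range. At the depth of 5.31e+06 to 2.24e+07 reads the models recovered 40 and 47 of 100 simulated changes of 1 log2 unit in left whole tissue and left cardiomyocytes, so changes of this size were often not detectable with 3 sheep per group.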

Other observations

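The tests of leaving out a sheep, of read depth and of a mixed-up sample below were set before their results were seen, although the genes used for the mixed-up sample were picked by limits chosen afterwards; the tests of effect size, of the posterior left atrium adjustment, of the other explanations for ENSOARG00000002796 and of the side-dependent genes, and all counts over other groupings of the sheep, were chosen only after the results were seen.

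Genes that are higher on the right than on the left in both appendage tables were followed in the posterior left atrium of the G sheep, none of which gave an appendage sample. Their median change in transition sheep, less that of other genes, was −0.48, and 82.4% of the 324 measured genes were lower, with a mean log2 CPM per sheep of 3.39 to 3.76 in 3 controls and 2.88 to 3.36 in 4 transition sheep. In an exact two-sided permutation test 3 of the 35 groupings gave a difference as large (p = 0.0857, adjusted p = 0.0857, smallest possible p 0.0286), so chance cannot be excluded in these sheep alone. Genes higher on the left had a difference of 0.222 in the same sheep, with 68.7% of 249 genes higher (exact p = 0.0286, the smallest possible, adjusted p = 0.0571). A general loss of side-specific expression would have lowered them. Their rise did not pass after adjustment, so it does not settle this question. A shift of the posterior left atrium away from right-sided expression in transition sheep may be a hypothesis to follow in more animals.

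In whole tissue of chronic sheep 924 genes passed on the left and 155 on the right, although 895 of the 924 (96.9%) had the same sign on the right and the test of the side difference itself called 0 genes. Leaving out sheep D15 brought the right count to 428, still below the left count divided by 1.5, and the left count without D15 was 933, which argues against a single sheep as the whole cause. Thinning the left libraries of 5 sheep to the depth of their right libraries left 939 genes, which argues against read depth. The spread of the chronic change beyond its error was 1.45 times larger on the left. With a sheep left out it was 1.23 times (without D15) to 1.63 times (without D16) larger. Both the gap in counts and this ratio were thus smaller without D15, so this sheep carries part of the asymmetry. A larger response on the left may be a candidate explanation, which rests on the same 3 chronic sheep and is untested in others.

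More genes passed for transition in the posterior left atrium (2109) than in left appendage whole tissue (184). The spread of the change beyond its error was 1.27 times larger in the posterior left atrium, but 1.15 to 1.62 times with a sheep of the appendage comparison left out, so larger changes cannot be told apart from the gain in precision of 12 sheep over 6, with median standard errors of 0.150 and 0.238. Of the genes called in the G sheep alone 95.8% had the same sign in the other set, against 69.8% of all genes. A shift of a whole set cancels in this comparison, so an adjustment by such a shift is unlikely to have made the changes. An adjustment that used the states could have raised this share. The step made before deposit is not recorded, so this cannot be excluded.

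ENSOARG00000002796, the only gene called between chronic and transition cardiomyocytes, had at most 2 reads in every library of sheep D16, D19 and D20 and 76 to 381 in every library of the other 8 sheep of the appendage tables. The chronic sheep D15, seen in whole tissue alone, had at least 268 reads, which argues against the chronic state as the cause, and in the posterior left atrium G32, G36 and G26, of both states, lay at −2.68 to −2.61 and the other sheep above 1.2, up to 5.18. With 0 sheep on in some libraries and off in others, a difference between animals may be a candidate explanation, for example a variant or a missing copy, neither of which was tested. The left and right cardiomyocytes of D19 differed at 29.2% of 24 other genes that are on in some sheep and off in others, which by the limit of 10% written beforehand fits a mixed-up sample, and the reading that it cannot be told was added after this value was seen. The cardiomyocytes of D16 and D20 differed at 4.55% each and matched their own sheep best, as did the whole tissue of D16 at 12.5%, which also lies above the limit. Over the 9 sheep of the cardiomyocyte table the median was 12.5%, so the limit does not single out D19. A mix-up of D19 stays open but alone would not account for the gene being off in D16 and D20 too.

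Over those on and off genes the left library closest to a right library came from the same sheep for 8 of 9 sheep in whole tissue and 7 of 9 in cardiomyocytes. Sheep D27 was the exception in whole tissue, with 35.3% of genes different from its own and 17.6% from the closest other sheep, and D27 (30.4% and 30.4%) and D19 (29.2% and 25.0%) were the exceptions in cardiomyocytes. A mix-up of D27 was not tested and stays open, also for the transition and left against right results, which include D27. The same holds for the tissue-enriched and cardiomyocyte-enriched lists made from transition sheep, which include D27. Those made from chronic sheep include D19. More genes differed between the sides in cardiomyocytes (2826) than in whole tissue (1059), with a spread of the difference beyond its error of 0.351 and 0.325, and no explanation was tested.

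Other groupings of the sheep were counted for each comparison. For left against right, 1 of 100 groupings with sides exchanged within sheep, the real one, gave as many genes, with 1059 against 443 in the highest other in whole tissue and 2826 against 853 in cardiomyocytes. Chance is thus unlikely to account for these counts. For the posterior left atrium 1 of 100 groupings of 6 sheep against 6, drawn without regard to the 2 sets of sheep, gave 2109 genes against 440 in the highest other. With states exchanged only within each set, 1 of 100 drawn of 350 groupings, the real one, gave as many, with 43 in the highest other. These values had been adjusted before deposit by an unrecorded step. If that step used the states, the real grouping was favoured, so these groupings cannot exclude chance. Comparisons of 3 sheep with 3 have 10 groupings, too few for a share under 0.05. In whole tissue the real and highest other counts were 184 and 1 for left transition, 924 and 0 for left chronic, 77 and 2 for right transition, 155 and 1 for right chronic, 0 and 2 for the side difference of the chronic change, and 0 and 1 and 0 and 7 for chronic against transition on the left and right. In cardiomyocytes they were 418 and 1, 938 and 0, 80 and 1 and 633 and 0 for the same comparisons with control, and 0 and 1 for the side difference of the transition change. For chronic against transition in cardiomyocytes 3 of 10 groupings gave 1 gene or more on the left, and 4 of 10 on the right, where the grouping of D16, D19 and D23 against D20, D24 and D27 gave 785 genes against 1 in the real one, which points to a structure of the samples other than the state. The same sheep lay apart in the right appendage on the first principal component of the cardiomyocytes.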
